A study of Mus musculus with 2 samples.

How the data were processed

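H3K9me3 ChIP-seq peaks of embryonic day 11.5 mouse forebrain were analysed for 2 biological replicates of 1 group, taken from the replicate numbers in the labels. Each replicate was a pool of many embryos of both sexes and combined 2 technical replicates. The authors deposited 4 peak lists in narrowPeak format on the mm10 assembly, per the file headers and the description deposited with the samples. Those descriptions state that each replicate list was called on that replicate's filtered alignments, the pooled list on the alignments of both replicates, and the replicated list was derived from the pooled list and both replicate lists. The rule that made a peak replicated, the aligner, the peak caller and their versions are not given in the sources used here. The labels name a possible control experiment, and how it entered peak calling is not given in the sources used here. The labels name sequencer models for replicate 1 only, and no sequencing date or batch.

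The values per peak are the authors' own. The deposited lists give a display score, an enrichment signal value, a −log10 p, a −log10 q and the summit of each peak. The deposited score was not used for any result. The signal value was planned as a fold enrichment, but no source names its scale, so it is called the authors' signal and is used only to describe, rank or filter peaks within a list and to describe shared peaks. The −log10 p and −log10 q values are as deposited by the authors, and the lists reach down to a −log10 p of about 2.02 to 2.05, so that many entries lie above a q of 0.05. The lists hold no read counts, so the depth of each library is unknown and no counting interval can be given. Signal tracks and alignments were not used here.

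Coordinates are 1-based. Sequence came from the mouse reference assembly GRCm38, whose chromosome lengths match mm10, and genes from release M21 of the GENCODE annotation of that assembly. Names of unlocalized and unplaced sequences could not be matched between the peak lists and the reference, so peaks there were counted but left out of all tests with genes, features or shifts. A gene held a peak where a peak touched its body or the 2 kb upstream by at least 1 bp. Promoters were 1 kb to either side of a transcription start site and took precedence over coding exons, UTRs, exons of noncoding transcripts, introns and intergenic sequence, in that order.

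Chance was estimated with a circular permutation test. On each chromosome, with runs of N removed, all peaks were moved by the same random distance and wrapped around the end, which keeps widths and spacing. There were 1000 shifts for overlaps, features and gene lists, and 100 for sequence content. Two-sided p-values were 2 times the smaller tail with 1 added to counts, so their smallest value is 0.002 (0.0198 for sequence). They were adjusted by the Benjamini-Hochberg method over the 17 gene lists and over the 6 features. Peak position within genes was tested with 100000 random sign flips over genes (10000 for the other genes) and the difference between gene sets with permutation of genes. Peaks within 10 kb were joined into domains. Because shifts keep spacing, the share of peaks in domains of 2 or more was set against 1000 random placements of each peak on its chromosome, a test chosen after seeing the data. Uniqueness of sequence was measured as the share of 36-mers under a peak that occur once in the assembly. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

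The gene lists, the tests, most alternatives and the rule for naming genes were set before the data were examined. The lists were zinc finger genes named Zfp, Zkscan, Zscan or alike, BTB zinc finger genes, clustered protocadherins, olfactory receptors, vomeronasal receptors, Hox genes, cytochrome P450 clusters, Rhox, Mage and Xlr genes, keratin genes, histone genes, Serpin genes, imprinted genes, germline genes, forebrain progenitor and neuron genes, genes of other cell types, housekeeping genes, and genes that write, read or erase H3K9 methylation. Families were taken by symbol patterns among protein-coding genes, which can include a member outside what the list's name says, and the other lists by symbol. All symbols were found except 1 of the 26 of the last list, and 2 of 329 vomeronasal genes lay off the assembled chromosomes. The rule named for each list the 4 members with the most bases under replicated peaks, all imprinted genes with a peak, the 20 other protein-coding genes with the most such bases, the 10 replicated peaks of highest signal, and the genes in the 10 domains with the most covered bases. Forebrain and Hox genes were named from the lists as examples.

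The shift test was tested on simulated peaks over the 21938 protein-coding genes with 200 shifts. It called 20 of 20 lists of 200 genes when peaks were planted at 30% of the genes of the list, 19 of 20 at 10%, and 0 of 20 with none planted. The background was the real peaks moved by 1 random shift, as in the test itself, and the lists were genes drawn at random. The simulation thus gives no error rate or power for clustered families or for much shorter lists. The sign-flip test called 46 of 50 simulated sets of 100 genes with a mean difference of 0.1 and an SD of 0.3, and 1 of 50 with no difference. The placement test with a gap of 10 kb called 200 of 200 simulated sets with planted pairs of peaks and 7 of 200 with none planted.

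Alternatives were a −log10 q of at least 5, other definitions of a shared peak, the pooled list, each replicate's list in place of the replicated list, other rules for assigning peaks to genes, Fisher's exact test against other protein-coding genes, 10000 random lists matched on gene length in 20 bins, other measures of position and other joining gaps. Added after seeing the data were a q of at most 0.05, replicated peaks that touch both replicate lists, and peaks with at least 90% unique 36-mers. Because the lists of a replicate differ in length from the replicated list, folds from them are not on the same footing.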

Results

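H3K9me3, the trimethylation of lysine 9 of histone H3 that marks heterochromatin, was profiled by ChIP-seq in the forebrain of mouse embryos of strain B6NCrl at embryonic day 11.5. There were 2 biological replicates in a single group. Replicate 1 was a pool of 109 embryos and replicate 2 a pool of 88 embryos, both of mixed sex, and each was made from 2 technical replicates. The data were lists of peaks on the mm10 assembly. There was a list for each replicate, a pooled list made from the alignments of both replicates together, and a replicated list that the authors derived from those 3. With a single group there was no contrast between conditions, and the questions the design allows are where the mark lay and how well the replicates matched. The depth behind each peak is unknown, because the lists hold no read counts.

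Most peaks of replicate 1 were found again in replicate 2, which yielded far more peaks. Replicate 1 had 5991 peaks that covered 1.76 Mb, with a median width of 231 bp. Replicate 2 had 40534 peaks that covered 14.0 Mb, with a median width of 269 bp, which is 6.77 times as many peaks. Of the 5765 replicate 1 peaks on assembled chromosomes, 4105 (71.2%) touched a peak of replicate 2 by at least 1 bp. When the peaks were slid along the chromosomes in 1000 circular shifts, a mean of 1.19% and at most 3.82% did so (one-sided permutation p = 0.001, the smallest these shifts can give). Of the 40259 replicate 2 peaks, 3747 (9.31%) touched a peak of replicate 1, against a mean of 0.172% in the shifts (permutation p = 0.001). The share of replicate 1 peaks was 27.4% when at least 50% of each peak had to be shared, and 36.9% against the 5765 strongest peaks of replicate 2. The Jaccard index of covered bases was 0.0810, against 0.000723 in the shifts (permutation p = 0.001).

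At the 4105 shared peaks the authors' enrichment signal was higher in replicate 2 at 81.4% of peaks, with medians of 3.25 in replicate 1 and 4.13 in replicate 2; no source says whether the 2 lists share a scale. Across these peaks, which are not independent replicates, the signal of the replicates had a Spearman correlation of 0.265 and a Pearson correlation of 0.385. At the 135 shared peaks that reached a −log10 q of 5 in both lists the Spearman correlation was 0.766. The peak lists also went far down in significance. The median −log10 q was 0.308 in replicate 1 and 1.65 in replicate 2, and 941 peaks (15.7%) of replicate 1 and 24238 (59.8%) of replicate 2 had a q of at most 0.05.

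The replicated list held 8514 peaks that covered 3.63 Mb, with a median width of 331.5 bp and an interquartile range of 253 to 462 bp. All 8514 were identical entries of the pooled list of 13806 peaks. It was not the intersection of the replicate lists: 8421 of its peaks (98.9%) touched a peak of replicate 2, 3865 (45.4%) touched one of replicate 1, and 3787 (44.5%) touched both. A q of at most 0.05 was reached by 2889 (33.9%) of them, and a −log10 q of at least 5 by 374. The 8292 replicated peaks on assembled chromosomes were used for the comparisons with genes that follow. The p-values of those comparisons measure chance placement along the genome, not the spread between replicates, so the values of each replicate's own list are given for the gene lists that passed the test, for coding exons and promoters, and for sequence content.

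Zinc finger genes held the mark more often than chance placement gave. Of 432 protein-coding genes with names of the Zfp, Zkscan or Zscan kind, many of which encode DNA-binding repressors with a KRAB domain, 121 (28.01%) held a replicated peak in the gene body or the 2 kb upstream. Shifted peaks reached 30.03 ± 8.59 of them (mean ± SD over 1000 shifts), a 4.03-fold difference (two-sided permutation p = 0.002, the smallest the shifts can give; Benjamini-Hochberg adjusted p = 0.0113 over 17 gene lists). The list of replicate 1 alone reached 87 of these genes (3.64-fold, adjusted permutation p = 0.0170) and that of replicate 2 alone 187 (1.84-fold, adjusted p = 0.0113). The 4 genes with the most marked bases were Zfp873 (chromosome 10, 82048123 to 82064745), Zfp180 (chromosome 7, 24081924 to 24107713), Zfp930 (chromosome 8, 69209038 to 69230536) and Zfp606 (chromosome 7, 12478293 to 12496235). In Zfp873, 13 peaks covered 11029 bp, which was 59.2% of the gene and its upstream sequence. In Zfp180, 12 peaks covered 10487 bp and the highest signal was 8.38, with 6.62 in replicate 1 and 11.1 in replicate 2. Peaks covered 8339 bp of Zfp930 and 7936 bp of Zfp606, and both replicates had peaks in each of these 4 genes. Of the 402 distinct replicated peaks at zinc finger genes, 208 (51.7%) touched peaks of both replicates. Another family of zinc finger genes, the 41 BTB genes named Zbtb, held 4 genes with a peak (1.31-fold, adjusted permutation p = 0.892): Zbtb40, Zbtb16, Zbtb7c and Zbtb20. None of the 4 had more than 611 bp covered.

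The mark lay toward the 3′ end of the zinc finger genes, where the exon coding for the zinc fingers usually lies. Among 117 zinc finger genes with a replicated peak in the body, with the body cut into 3 equal parts, peaks covered 15.2 percentage points more of the part at the 3′ end than of the part at the 5′ end (SD 20.3). The difference was positive in 82 genes, negative in 23 and zero in 12 (two-sided sign-flip permutation test, p = 1e-05, the smallest it can give). It was 10.2 points in the list of replicate 1 alone (SD 14.7, n = 83) and 14.3 points in that of replicate 2 alone (SD 21.9, n = 183). In 1580 other protein-coding genes with a peak the difference was −1.28 points (SD 15.1; sign-flip permutation p = 0.0016). The 2 sets of genes differed by 16.5 points (permutation p = 1e-05). These tests take genes as independent, but neighbouring or overlapping genes can share peaks, so their p-values may be too small. With 1 zinc finger gene kept per cluster, the difference in these genes was 13.1 points (SD 19.9, n = 89, sign-flip permutation p = 1e-05). The other genes were not reduced in this way. Along the body, mean coverage in zinc finger genes went from 0.596% ± 0.435 (SE) in the first of 20 parts to 25.9% ± 3.32 in part 19. Coding exons held the summits of 95 (23.6%) of the 402 peaks at zinc finger genes and of 314 (3.79%) of all 8292 replicated peaks. Introns held more of the summits at zinc finger genes than coding exons did, 194 (48.3%), and promoters held 45 (11.2%). Of all replicated peaks, introns held 2733 (33.0%) and promoters 871 (10.5%). However, 4058 of all replicated peaks had an intergenic summit, against 5 at zinc finger genes, which were chosen for lying at a gene. Among summits outside intergenic sequence, the coding exon share was still higher at zinc finger genes, but the intron and promoter shares were lower. These shares were not tested. At the annotated 5′ end of the gene, by contrast, zinc finger genes were not marked beyond chance: within 1 kb of it, 5 of 432 held a peak (1.14-fold, adjusted permutation p = 1). This test used a single start per gene, whereas the promoter class above used the start of every transcript.

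**Figure D1:**
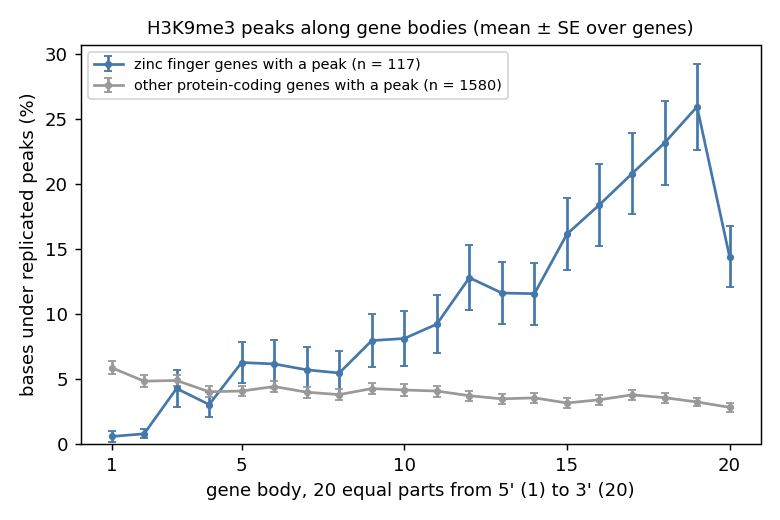
Mean share of bases under replicated H3K9me3 peaks (y axis, percent) in 20 equal parts of the gene body from the 5′ end to the 3′ end (x axis), with bars of 1 standard error over genes. Blue points are 117 zinc finger genes with a peak and grey points 1580 other protein-coding genes with a peak; the zinc finger genes rise to 25.9% in part 19 while the other genes stay below 6%.

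**Figure D2:**
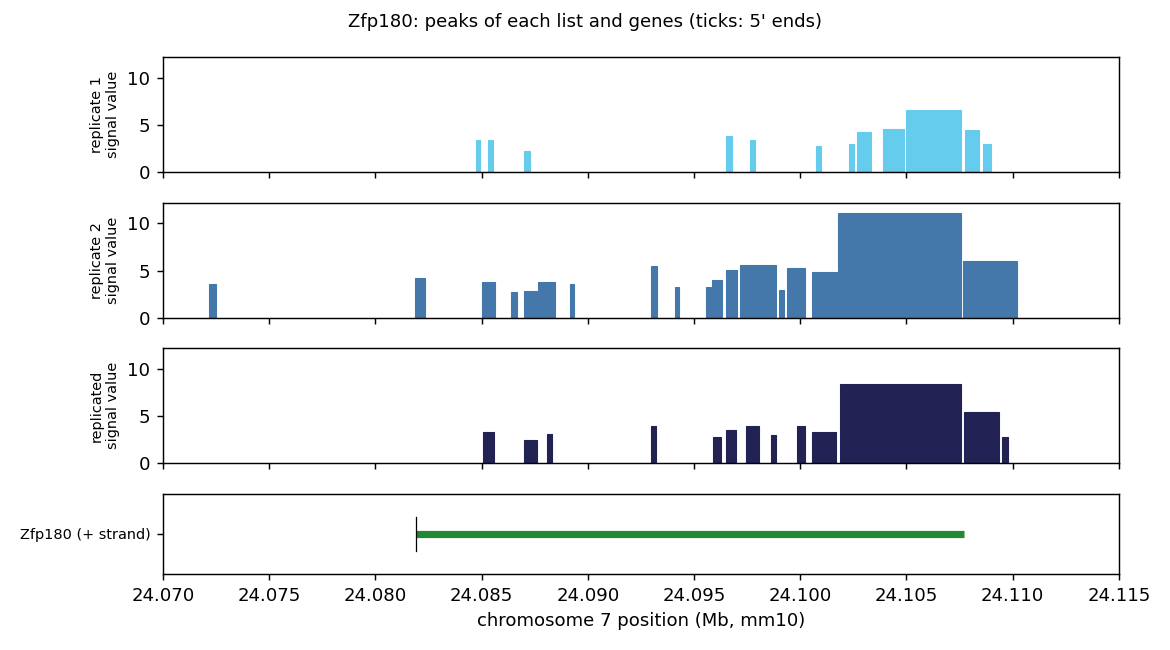
Peaks of replicate 1, of replicate 2 and of the replicated list around Zfp180 (chromosome 7, mm10, x axis in Mb), each drawn as a bar over its width with the authors' signal value as its height (y axis). The gene lies on the plus strand, with its 5′ end as a tick, and the strongest peak of all 3 rows lies at its 3′ end, at 8.38 in the replicated list.

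The clustered protocadherins, cell adhesion proteins of which each neuron uses a few, nearly all carried the mark. Of 57 genes, 52 (91.2%) held a replicated peak, against 6.49 ± 9.01 in the shifts (8.01-fold, adjusted permutation p = 0.0113). By cluster these were 12 of 14 alpha, 22 of 22 beta and 18 of 21 gamma genes. The lists of replicate 1 and replicate 2 alone reached 48 genes (8.64-fold, adjusted permutation p = 0.0226) and 53 genes (2.23-fold, adjusted p = 0.0113). The cluster held 184 distinct replicated peaks, of which 76 (41.3%) had their summit within 1 kb of a transcription start site and 50 (27.2%) in a coding exon. The mark was present at the starts of the variable exons: within 1 kb of the start, 47 of the 57 genes held a peak, against a mean of 0.359 in the shifts. Gene bodies in the alpha and gamma clusters are nested, so neighbouring members share peaks. The 4 members with the most marked bases, Pcdhga1, Pcdhga2, Pcdhga3 and Pcdhgb1, are of this kind; Pcdhga1 (chromosome 18, 37661793 to 37841873) held 70 peaks over 66456 bp, with a highest signal of 7.31. The median signal was 3.94 at the gamma peaks, 3.52 at the alpha peaks and 3.29 at the beta peaks. Peaks touching both replicates made up 75.7% of the gamma, 53.1% of the alpha and 36.9% of the beta peaks; these differences between clusters were not tested. Restricted to peaks with a −log10 q of at least 5, which left 284 peaks on chromosomes, 18 protocadherins held a peak, against a mean of 0.201 in the shifts (89.6-fold, adjusted permutation p = 0.0849).

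**Figure D3:**
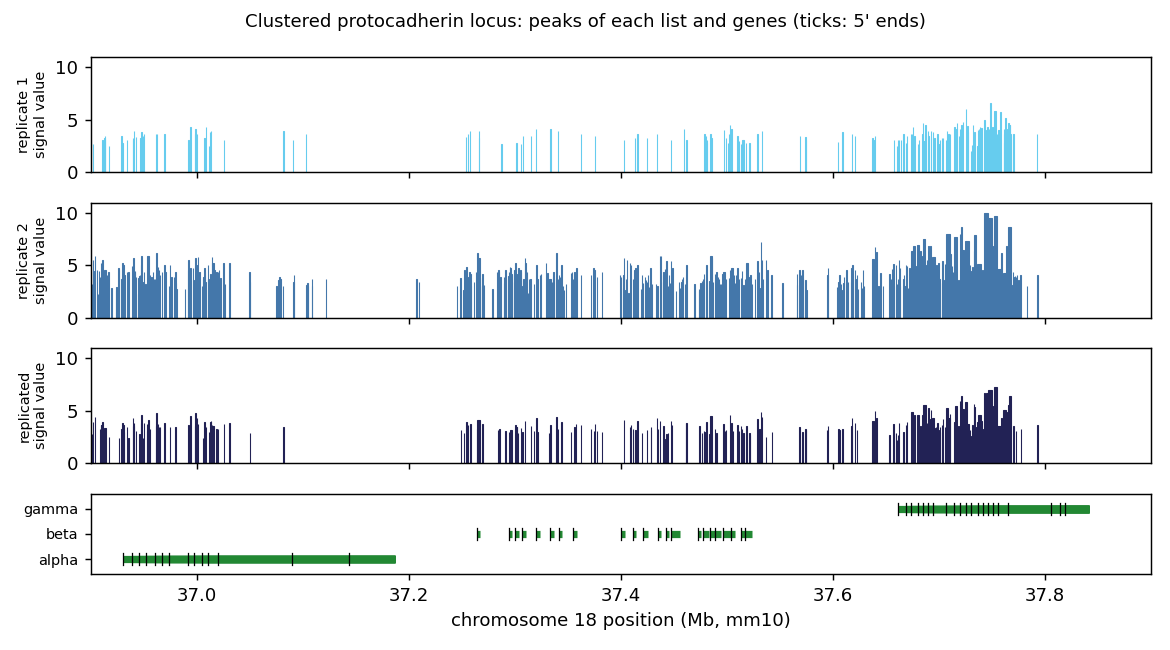
Peaks of replicate 1 (177), replicate 2 (443) and the replicated list (245) over the clustered protocadherin locus on chromosome 18 (mm10, x axis in Mb), drawn as bars over their width with the authors' signal value as height (y axis). Green bars below are the alpha, beta and gamma genes with their 5′ ends as ticks; the highest replicated signal in the region, 7.31, lies over the gamma genes.

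Imprinted genes, which are expressed from a single parental allele, held the mark in most of the listed genes. Of 45 genes, 31 (68.9%) held a replicated peak, against 4.86 ± 2.23 in the shifts (6.38-fold, adjusted permutation p = 0.0113). Because neighbouring or overlapping genes shared peaks, the 31 genes fell into 21 groups with no peak in common, 10 of them pairs. The list of replicate 1 alone reached 25 genes (6.13-fold, adjusted permutation p = 0.0170) and that of replicate 2 alone 38 (2.69-fold, adjusted p = 0.0113). Of the 67 distinct peaks, 46 (68.7%) had their summit within 1 kb of a transcription start site, compared with 10.5% of all replicated peaks, and 42 (62.7%) touched peaks of both replicates. Among all 8292 replicated peaks 4058 had an intergenic summit, so the 10.5% is low for peaks at genes. The most marked bases lay in Gnas (chromosome 2, 174284320 to 174346744; 5218 bp), which encodes the stimulatory G protein alpha subunit, and in Mest (chromosome 6, 30723547 to 30748465; 3593 bp). They were followed by Peg3 (chromosome 7, 6703892 to 6730431; 3330 bp), which encodes a zinc finger protein, and Peg10 (chromosome 6, 4747306 to 4760517; 3108 bp), which derives from a retrotransposon. Grb10, an adaptor of growth factor receptors, had 2875 bp covered, and Cdkn1c, a cyclin-dependent kinase inhibitor, 2019 bp. The highest signal in the list, 4.93, was at Nnat (chromosome 2, 157560078 to 157562522), which lies within Blcap and shares its 3 peaks. Besides Mest, Grb10 and Cdkn1c, the genes that shared no peak with another of the list were the maternally expressed Meg3 and Rian RNAs, Inpp5f, Impact, Plagl1, Slc38a4, Ube3a and Ndn. Gnas shared peaks with Nespas, which is antisense to it, Peg3 with Usp29, and Peg10 with Sgce. The remaining pairs with shared peaks were Peg13 and Trappc9, Kcnq1 and Kcnq1ot1, Airn and Igf2r, Commd1 and Zrsr1, Herc3 and Nap1l5, and Snrpn and Snurf. Replicate 1 had no peak of its own at Airn, Igf2r, Snrpn, Snurf, Slc38a4 or Ndn. The peaks were of moderate to low strength: 34 of the 67 had a q of at most 0.05. Peaks of that kind reached 25 of the 45 genes (12.5-fold, adjusted permutation p = 0.0113). The highest −log10 q was 0 at Slc38a4, 0.567 at Snrpn, Snurf, Herc3 and Nap1l5, and 0.700 at Ube3a. None of the peaks reached a −log10 q of 5, so that the count was 0 of 45 at that threshold.

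A minority of germline genes held a peak. Of 40 genes, 9 (22.5%) held a replicated peak, against 3.11 ± 1.66 in the shifts (2.89-fold, adjusted permutation p = 0.0340), and each held a single one. Of the 9 peaks, 7 had their summit within 1 kb of a transcription start site and 2 in an intron. Within 1 kb of their own start, 6 of the 40 genes held a peak (21.7-fold, adjusted permutation p = 0.0113). The most bases were covered in Meioc, a meiosis gene (chromosome 11, 102663716 to 102682237; 1266 bp, signal 4.28), and Dazl, an RNA-binding protein of germ cells (chromosome 17, 50279395 to 50293636; 1064 bp, signal 5.25). Ddx4, a germ cell RNA helicase, had 808 bp covered and the X-linked Taf7l 706 bp. The list of replicate 1 alone reached 6 genes and did not pass the test (2.45-fold, adjusted permutation p = 0.159), while that of replicate 2 alone reached 21 (1.81-fold, adjusted p = 0.0272). Replicated peaks that touched both replicate lists reached 5 genes (3.32-fold, adjusted permutation p = 0.0951), those with a q of at most 0.05 reached 6 (5.21-fold, adjusted p = 0.0170), and those with a −log10 q of at least 5 reached 1 (12.7-fold, adjusted p = 0.815).

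Among the other clustered gene families, the vomeronasal receptors passed the shift test and the others did not. Of 327 vomeronasal receptor genes, 50 (15.3%) held a replicated peak, against 18.7 ± 8.02 in the shifts (2.68-fold, adjusted permutation p = 0.0340). Vmn2r16 (chromosome 5, 109330162 to 109370247) had 3640 bp covered, Vmn2r53 (chromosome 7, 12562851 to 12608788) 2973 bp, and the overlapping Vmn1r42 and Vmn1r43 on chromosome 6 shared 2163 bp. The list of replicate 1 alone reached 36 genes (2.56-fold, adjusted permutation p = 0.0594) and that of replicate 2 alone 110 (1.78-fold, adjusted p = 0.0272). The call was also lost with a q of at most 0.05 (2.74-fold, adjusted permutation p = 0.0815), with peaks that touched both lists (2.72-fold, adjusted p = 0.0594) and within 1 kb of the start (3.29-fold, adjusted p = 0.127), and no gene held a peak with a −log10 q of at least 5. Olfactory receptors held peaks in 53 of 1093 genes (1.88-fold, adjusted permutation p = 0.301), most bases in Olfr1349 (2216 bp) and Olfr398 (1892 bp). Their share was 0.580 times that of all other protein-coding genes (Fisher's exact test, adjusted p = 5.3e-05) but 1.39 times that of random lists matched on gene length (adjusted p = 0.0391). Cytochrome P450 genes of the Cyp2, Cyp3 and Cyp4 families held peaks in 11 of 77 (1.98-fold, adjusted permutation p = 0.391), led by Cyp3a11 (3063 bp), Cyp3a57 (2309 bp), Cyp3a16 and Cyp2b13. Against random lists matched on gene length their fold was 2.29 and did pass (adjusted permutation p = 0.0391). Serpin genes held peaks in 3 of 50 (Serpinb6d, Serpina1e and Serpina9; 1.65-fold, adjusted permutation p = 0.803), and the X-linked Rhox, Mage and Xlr genes in 1 of 58 (Rhox13; 2.97-fold, adjusted p = 0.803). None of 110 keratin and keratin-associated genes held a replicated peak (shift mean 1.36, adjusted permutation p = 0.886), and 1 of 95 histone genes did (shift mean 0.987, adjusted p = 1). By Fisher's exact test against all other protein-coding genes, both of these lists were below them (adjusted p = 0.000436 and 0.0095), but against random lists matched on gene length neither passed (adjusted p = 0.197 and 0.859). The marked gene of the histone list, H2afy2, encodes a macroH2A variant and not a replication-dependent histone.

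No replicated peak lay at the listed forebrain, Hox, other cell type or housekeeping genes, which chance placement also seldom reached. None of 36 forebrain progenitor and neuron genes, among them the transcription factors Foxg1, Pax6, Emx2 and Dlx2, held one, and none of 39 Hox genes, which pattern the trunk and hindbrain, did. None of 45 marker genes of other cell types (endothelium, blood, mesenchyme, liver, muscle and pluripotent cells among them) and none of 30 housekeeping genes held one either. These counts did not differ from the shifts, because the shifts reached few of these genes: 1.64 forebrain genes (adjusted permutation p = 0.498), 0.727 Hox genes (adjusted p = 1), 2.55 genes of other cell types (adjusted p = 0.301) and 1.08 housekeeping genes (adjusted p = 0.886). The list of replicate 1 alone reached 1 forebrain gene and 1 Hox gene (adjusted permutation p = 1 for each) and none of the genes of other cell types or the housekeeping genes. The longer list of replicate 2 alone reached 2 of the forebrain genes, 1 Hox gene, 9 genes of other cell types and 3 housekeeping genes, again without passing the test. Of 25 genes that write, read or erase H3K9 methylation, 3 held a peak (1.36-fold, adjusted permutation p = 0.892): Atf7ip, a partner of the methyltransferase Setdb1 (1108 bp covered), Smchd1 (368 bp) and Morc3 (294 bp). In all, 1797 of 21938 protein-coding genes (8.19%) held a replicated peak.

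**Figure D4:**
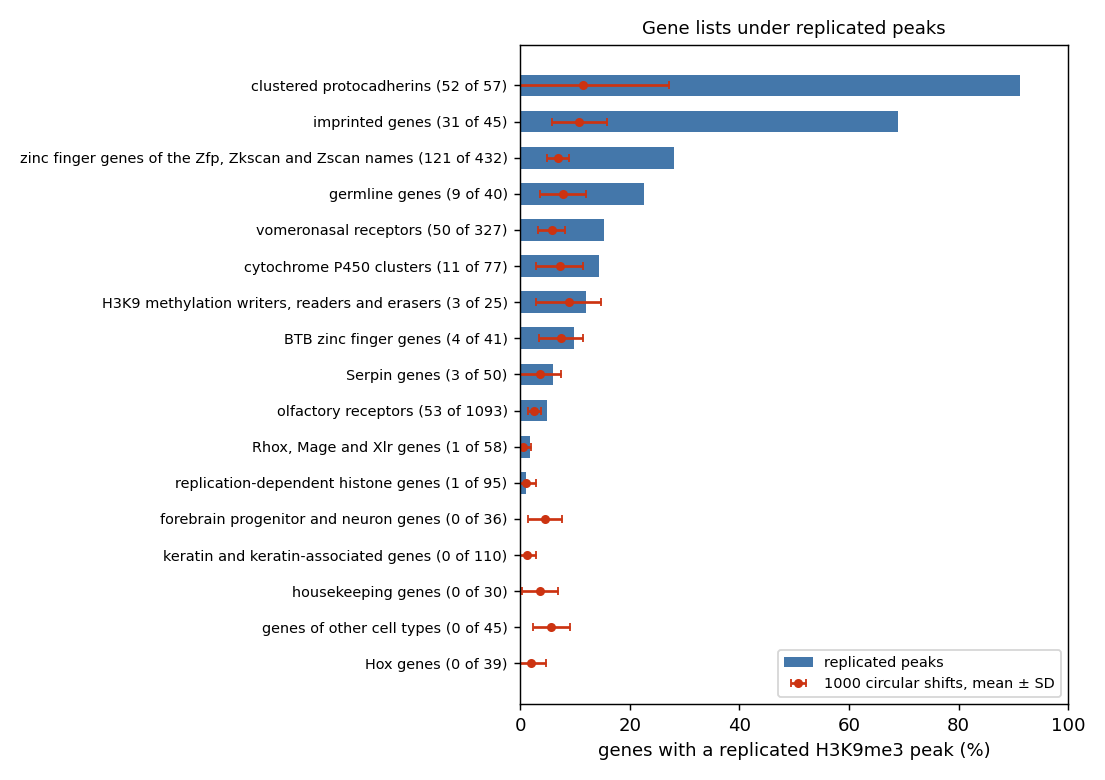
Share of genes with a replicated H3K9me3 peak in the body or 2 kb upstream (bars, x axis in percent) for the 17 gene lists, with the number of genes in brackets. Red points and bars are the mean ± SD over 1000 circular shifts; clustered protocadherins (91.2%), imprinted genes (68.9%) and zinc finger genes (28.01%) lie far to the right of their shifts, and 5 lists stand at 0.

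Outside the lists, the most marked protein-coding genes fell into a few loci. Gm42416 (chromosome 18, 36952741 to 37840200), Gm37013 (36969916 to 37833296) and Gm37388 (36975941 to 37833296) overlap one another, start within the alpha and end within the gamma protocadherins, and held 221, 211 and 210 replicated peaks. On chromosome 1, Mroh2a (88226986 to 88262289) was covered over 34190 bp, or 91.7% of the gene and its upstream sequence. The neighbouring cold-sensing channel gene Trpm8 (88277661 to 88389293) was covered over 23428 bp. The glucuronosyltransferase genes Ugt1a2, Ugt1a5, Ugt1a6a, Ugt1a6b, Ugt1a7c, Ugt1a8, Ugt1a9 and Ugt1a10 end at the same place and share peaks there (7886 to 9157 bp). On chromosome 11, the overlapping Drg1 and Sfi1 had 11468 and 11151 bp covered, with signals of at most 3.07 and 4.60 and −log10 q values of 40.5 and 47.3. The highest signal and −log10 q were 4.65 and 15.5 in Mroh2a, 4.43 and 13.6 in Trpm8, and 4.41 and 19.2 in the Ugt1a genes. Zfp180, with a signal of 8.38, had a −log10 q of 21.9, and the imprinted gene Mest, with a signal of 4.77, had 4.71. Why significance was so high at the signals of the chromosome 1 and chromosome 11 genes was not tested. Further genes were the ubiquitin ligase gene Mid1 on the X chromosome (8766 bp, signal 7.17), the oocyte gene Nlrp5 (7784 bp), the transcription cofactor gene Trim24 (7463 bp, signal 7.74), the homeobox gene Zfhx3 (7462 bp) and Gm20388, annotated over 4434882 bp of chromosome 8 (7252 bp).

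The strongest replicated peak lay on chromosome 18 (3117848 to 3119135), between genes and 3357 bp from Vmn1r238, with a signal of 13.5, and 10.7 and 16.7 in replicates 1 and 2. The next was in a UTR of the kinase gene Peak1 on chromosome 9 (56318519 to 56318958, signal 9.88), and a coding exon of the same gene held another of the 10 strongest (56260268 to 56260875, signal 8.18). After the first of these came a peak in an intron of C230088H06Rik and Gm26624 on chromosome 4 (147335883 to 147336666, signal 8.78). It was followed by the promoters of Ccdc177 (chromosome 12, 80756982 to 80759326, signal 8.74) and of the testis factor gene Tcfl5 (chromosome 2, 180642741 to 180643532, signal 8.72). Others lay in the coding exon of Zfp180, in a UTR of Zfp810 on chromosome 9 (22276833 to 22277943, signal 7.84) and in a noncoding exon at Tmem267 on chromosome 13 (119494846 to 119495265, signal 7.79). The remaining peak lay on an unlocalized sequence of chromosome 4 (signal 8.46). Of the 9 on assembled chromosomes, 4 had fewer than 90% of their 36-mers unique in the assembly: those at Vmn1r238 (80.4%), at Peak1 with signal 9.88 (89.6%), at C230088H06Rik (69.6%) and at Tmem267 (31.7%). These 9 belong to the top 1% of peaks by signal. Peaks of the top 1% lay within 1 Mb of the start of the sequenced chromosome more often than the others (16.9% against 4.06%, tested below).

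Most bases under replicated peaks were intergenic (45.5%) or intronic (32.3%), while exons and promoters held more of them than chance placement gave. Coding exons made up 5.50% of the bases under peaks, against 1.06% ± 0.130 in the shifts (5.21-fold, adjusted permutation p = 0.0024 over 6 features). The fold was 5.57 in replicate 1 alone and 2.51 in replicate 2 alone. Of the 314 replicated peaks with their summit in a coding exon, 95 lay at the listed zinc finger genes and 50 at the clustered protocadherins. No fold was computed without these families. Promoters, taken as 1 kb to either side of a transcription start site, made up 12.5%, against 6.66% ± 0.564 (1.87-fold, adjusted permutation p = 0.0024), with 1.94-fold in replicate 1 alone and 1.34-fold in replicate 2 alone. UTRs (1.73-fold) and exons of noncoding transcripts (1.74-fold) were also above the shifts, and introns were below them at 32.3% against 40.0% (0.808-fold), all with an adjusted p of 0.0024. Intergenic sequence, at 45.5% against 49.8%, did not pass the test (0.912-fold, adjusted permutation p = 0.0779), but did so among peaks with a −log10 q of at least 5 (0.508-fold, adjusted p = 0.0030). At that threshold introns (0.861-fold) and exons of noncoding transcripts (1.14-fold) no longer passed (adjusted permutation p = 0.685 for each). The sequence under peaks was richer in GC than shifted sequence (46.9% against 42.1%) and poorer in annotated repeats (22.6% soft-masked against 33.9%), each with permutation p = 0.0198, the smallest that 100 shifts can give. GC was 47.9% in replicate 1 alone and 45.5% in replicate 2 alone, and the soft-masked share 20.6% and 26.3%. Of the 36-mers under replicated peaks 97.3% occurred once in the assembly, and the shifts were not limited to unique sequence. The lower soft-masked share therefore does not show that the mark avoids repeats. The same shifts were used for the feature and GC comparisons, so this limit applies to them as well. The CpG observed over expected ratio was 0.211 against 0.193 (permutation p = 0.0198), but its direction differed between replicates: in replicate 1 alone it was 0.223 and in replicate 2 alone 0.182, above and below the shifts (permutation p = 0.0198 for each). In the pooled list it was 0.198 and did not pass (adjusted permutation p = 0.238).

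Replicated peaks lay closer together than single peaks placed at random. Joined over gaps of at most 10 kb, they formed 4726 domains, of which 1125 held 2 or more peaks, and these held 56.6% of the peaks. With each peak placed at random on its chromosome 1000 times, the share was 8.81% ± 0.415 (mean ± SD; one-sided permutation p = 0.001). The share depended on the gap: it was 34.5% with 1 kb (1.26% at random) and 71.4% with 50 kb (34.5% at random). A broad region split into several peaks would by itself raise the share, and the placements cannot tell this from separate regions that lie close. The domain with the most covered bases (chromosome 1, 88204623 to 88310905) held 43 peaks over 71423 bp and spanned the 3′ part of the Ugt1a genes with Dnajb3, Mroh2a, Trpm8 and Hjurp, the chaperone of the centromeric histone. The second (chromosome 18, 37653639 to 37777633) held 72 peaks over 67017 bp in the gamma protocadherins, and the tenth (37474157 to 37542939) 32 peaks over 15776 bp in the beta protocadherins. Zinc finger genes lay in 2 of the 10: Zfp369 with Gm10775 on chromosome 13 (65237343 to 65312079, 38 peaks) and Zfp110 with Zfp329 on chromosome 7 (12808470 to 12869797, 31 peaks). The sperm motility kinase genes Smok2a and Smok2b lay in another (chromosome 17, 13195485 to 13239793, 27 peaks). The other 4 held no protein-coding gene, and 3 of them lay within 1 Mb of the start of the sequenced part of chromosomes 3 (3000429 to 3042095), 4 (3050001 to 3091119) and 16 (3231554 to 3284533).

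Chromosome 7 stood out with 9.74 replicated peaks per Mb of sequence, 2.85 times the autosomal 3.42. It was followed by chromosomes 17 (5.29), 18 (5.03) and 4 (4.90). The X chromosome, in these pools of mixed sex, held 92 peaks or 0.563 per Mb, 0.165 times the autosomal density, and the Y chromosome held 6. Chromosome 7 had the highest density in both replicates, at 2.46 times the autosomes in replicate 1 and 2.50 times in replicate 2. The X ratio was 0.214 in replicate 1 and 0.278 in replicate 2. No test was made for chromosomes.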

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

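A signal was present in data that no comparison used. Of the 8514 replicated peaks, 222 (2.61%) lay on unlocalized or unplaced sequences, 49 of them on Un_JH584304 and 32 on Un_GL456393. The replicate lists held 226 (3.77%) and 275 (0.678%) such peaks. Among peaks with a −log10 q of at least 5, these sequences held 90 of the 374 replicated peaks. They held 49 of 192 such peaks in replicate 1 and 147 of 2675 in replicate 2. The peaks on these sequences could not be joined to the annotation and no explanation was tested for them.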

How the results depend on the processing

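Of 308 alternatives, 271 stayed on the same side of the threshold, or kept the size where there was no test. Where neither value passed, the direction could differ, so these 271 did not all keep it. The Jaccard index does not depend on how a shared peak is defined, so the 50% rules could not change it. The zinc finger list passed at 1.84 to 29.3-fold in all alternatives but the start sites, protocadherins at 2.23 to 131-fold in all but the strictest threshold, imprinted genes at 2.69 to 29.2-fold in all but that threshold, and the difference in position within zinc finger genes stayed at 10.2 to 24.7 points with permutation p = 1e-05. The alternatives q of at most 0.05, both replicate lists touched and unique 36-mers were chosen after seeing the data. At a −log10 q of at least 5 there were 192 peaks in replicate 1, 2675 in replicate 2, 380 pooled and 374 replicated, and at a q of at most 0.05 there were 941, 24238, 3124 and 2889. The Spearman correlation of signal was 0.304 with 50% of each peak shared and 0.766 at a −log10 q of 5. With the 284 replicated peaks on chromosomes at that threshold, protocadherins had 89.6-fold (adjusted permutation p = 0.0849), germline genes 12.7-fold (0.815), vomeronasal receptors and imprinted genes 0 genes, intergenic sequence 0.508-fold (0.0030), introns 0.861-fold (0.685) and noncoding exons 1.14-fold (0.685); the fewer peaks lower what the test can call. The vomeronasal call was lost with a q of at most 0.05 (2.74-fold, adjusted permutation p = 0.0815), with peaks that touched both lists (2.72-fold, 0.0594) and with start sites only (3.29-fold, 0.127). The germline call was lost with peaks that touched both lists (3.32-fold, adjusted permutation p = 0.0951), and the zinc finger call with start sites only (1.14-fold, 1). Intergenic sequence passed with a q of at most 0.05 (0.752-fold, adjusted permutation p = 0.0030) and with both lists touched (0.841-fold, 0.0160). The X density ratio was 0.276 with a q of at most 0.05. With a joining gap of 1 kb, 34.5% of peaks lay in domains of 2 or more. The CpG ratio was 0.198 in the pooled list and lost its call (adjusted permutation p = 0.238). Lists that did not pass the shift test passed Fisher's exact test with ratios of 0.580 for olfactory receptors, 0.128 for histone genes and 0 for keratin genes, and passed against length-matched lists with 1.39 for olfactory receptors and 2.29 for cytochrome P450 genes; the shift test also keeps the spacing of peaks, which these do not. From the lists of single replicates, the ranges were 1.78 to 2.56 for vomeronasal and 1.81 to 2.45 for germline folds, both of which passed in replicate 2 but not in replicate 1, 0.882 to 1.03 for intergenic sequence, which passed in replicate 1 only, 0.182 to 0.223 for the CpG ratio and 0.214 to 0.278 for the X density ratio. Otherwise the cause was not tested. Leaving out a replicate gives no value for the overlap between replicates. No paired analysis was possible because there is a single group. Unknown depth limits what the absence of a peak can show.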

Other observations

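Some tests below were chosen after the results were seen. They were position within zinc finger genes for replicate 2 peaks that touched no replicate 1 peak, chromosome starts, and gaps inside chromosomes. The share of unique 36-mers among the strongest peaks was also chosen then.

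Genes without a family name carried the mark beside the named zinc finger genes. Gm4924 (chromosome 10, 82354255 to 82422882) had 6814 bp under replicated peaks, Gm10778 (chromosome 10, 81649059 to 81667361) 3349 bp and Gm35315 (chromosome 5, 110076136 to 110094420) 1358 bp, and the reference annotation gives each a zinc finger product. As a hypothesis, unnamed Gm genes with a zinc finger product may hold peaks as the named ones do. A replicated peak was held by 3 of 17 Gm genes with such a product (17.6%) and by 15 of 631 others (2.38%), a ratio of 7.42 (Fisher's exact test, p = 0.0096). The test is void, because only 648 of 1506 Gm genes (43.0%) could be matched to a product, so the hypothesis stays open.

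Replicate 2 had 6.77 times as many peaks as replicate 1. If its extra peaks lay at random they would not favour zinc finger genes, but the 36634 peaks of replicate 2 that touched no replicate 1 peak reached 180 of these genes against 98.9 in the shifts (1.82-fold, permutation p = 0.002; 2-fold had been set in advance to exclude it). They also covered 5.65 points more at the 3′ than at the 5′ end, by 3 equal parts of the body, in 177 zinc finger genes (sign-flip permutation p = 1e-05), so random placement does not account for all of them, although a part at random stays open. Whether replicate 1 held the same regions at lower signal stays open: the median signal ratio was 1.28 at 4105 shared peaks, but the lists have no known common scale, and weak peaks would be touched less often (4.37% of the lowest 10% of replicate 2 peaks by signal, 32.9% of the highest 10%) if they were noise as well. Whether depth, the immunoprecipitation or the embryos made that difference was not tested, since no read counts are known.

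Zinc finger genes held 4.03 times as many genes with a replicated peak as the shifts gave, and the values argue against both technical explanations that were tested. Reads shared between paralogs would make it vanish among peaks with at least 90% unique 36-mers, but these 7706 peaks reached 117 zinc finger genes against 28.98 in the shifts (4.04-fold, permutation p = 0.002). The 36-mers were matched exactly and within the assembly, so nearly identical copies and copies missing from the assembly are not covered. A single chromosome did not carry it either: the lowest fold with a chromosome left out was 3.76, without chromosome 9 (permutation p = 0.002). A bias of the control or of GC content stays open, and no biological explanation was tested, since the design has a single group.

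The strongest replicated peaks lay beside gaps in the assembly more often than the others. Of the top 1% by signal (83 peaks), 24.1% lay within 100 kb of a run of at least 1000 N, against 4.46% of the others (ratio 5.40, Fisher's exact test, p = 7.7e-10), which is consistent with collapsed repeats beside gaps. Pericentromeric sequence may account for a part: 16.9% lay within 1 Mb of the start of the sequenced chromosome, against 4.06% of the others (ratio 4.16, Fisher's exact test, p = 7.4e-06). Without those first megabases the ratio for gaps was 3.47 (7 of 69 peaks, Fisher's exact test, p = 0.0043), so both explanations remain, and no biological explanation was tested. Of these 83 peaks 23 (27.7%) had fewer than 90% unique 36-mers, against 6.86% of the others. Fisher's exact test takes peaks as independent, but 56.6% of replicated peaks lay in domains of 2 or more. Its p-values for the strongest peaks may therefore be too small.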
